A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

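The series compared Rad52 chromatin immunoprecipitation in 2 fission yeast strains in a cdc25-22 background, with 3 arrays labelled WT and 3 labelled Δrad3. Each array was hybridised with input DNA in the 647 (red) channel and IP DNA in the 555 (green) channel, per the labels, and the ratio was turned to IP over input on that basis. The series text speaks of reciprocal labelling, but the labels give every array the same orientation, so dye bias was not removed within a strain. All pairs of arrays correlated positively over bins (0.0876 to 0.604), at 0.284 to 0.453 within WT and 0.514 to 0.604 within Δrad3. The protocol texts differ between labels: WT replicates 1 and 2 carry a chromatin text with fragments of 400 to 500 bp and an anti-Rad52 antibody. WT replicate 3 and all Δrad3 samples carry an RNA text, with hydroxyurea added 10 min after release. That text was taken as a copy from another series, since the series is ChIP-on-chip. Samples were grouped by strain from the labels alone.

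The deposited files are Agilent Feature Extraction 10.7.3.1 output of 2-colour tiling arrays, named in the submitters' processing notes and per the file headers, with 45220 spots, of which 2513 are controls and 42707 are probes. Probes are 45 to 60 nt long with a median spacing of 265 bp. The intensity columns hold spot brightness on a linear scale, and the processed intensity was background-subtracted, spatially detrended and linearly dye-normalized within each array by the authors' run of Feature Extraction, per the file headers. The lowess dye terms are 0 on every array. The deposited log10 ratio is red over green, and it matched the ratio of the processed signals for 99.9% of probes on WT replicate 3, the lowest share. The log2 values were computed here from the deposited processed signals. Headers name a CGH protocol for slides 1 and 3 and a ChIP protocol for slide 2. The files hold median and not mean spot signals. No further normalization between arrays is given in the sources used here.

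For each array, log2 IP/input was centred on its median, with no loess or quantile step. Control spots and spots marked by the software as non-uniform or population outliers were left out (4, 464 and 212 on the arrays labelled WT, and 147, 3535 and 431 on Δrad3). Saturated spots were kept. Probes were kept where the input was well above background on at least 3 of 6 arrays (42659), and averaged in 1-kb bins with at least 2 probes (12058 bins). Between 97.9% and 99.9% of probes were well above background in the input on each array, and 94.1% to 99.9% in the IP. Both strains entered 1 limma fit with 4 residual degrees of freedom before moderation. A bin was called enriched in a strain at a Benjamini-Hochberg adjusted p under 0.05 and a mean log2 of at least 0.5, and different between strains at an adjusted p under 0.05. Region lists were tested with fry and camera (preset correlation 0.01, and estimated) and with exact two-sided permutation tests of array means. Enrichment at islands was set against 10259 annotated bins. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

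Coordinates are those of the files, whose headers give the build as Spombe:NCBI:Feb2002. Gene names came from the ASM294v3 annotation, after probe lengths, which follow base composition, were correlated with the A+T content of that sequence at a range of shifts in windows of 100000 bp. All 108 windows used matched within 20 bp without a shift. On chromosome I beyond 3.7 Mb, 18 of 19 windows matched best at a shift of about 6150 bp, so its 6236 probes (14.6%) stayed in the tests without names and no coordinate was converted. AT-rich islands were windows of 1000 bp in steps of 50 bp with at least 72% A+T, merged, and at least 50% outside coding sequence. This gave 369 islands of median length 1350 bp, and the 322 measured bins that hold an island midpoint made up the list. The A+T regression left out probes without a name, and so chromosome I beyond 3.7 Mb.

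The lists, tests, groups and alternatives, and the rule for named regions, were fixed before the data were examined. The lists were AT-rich islands, centromeres, subtelomeres (50 kb), divergent and convergent intergenic regions, the mitochondrial genome, and genes for tRNA, rRNA and 5S rRNA, snRNA and snoRNA, histones, heat shock proteins, ribosomal proteins, glycolysis and fermentation, MBF targets and meiosis-specific functions. Centromeres were those of chromosomes II and III, and subtelomeres the ends of chromosomes I and II. Intergenic regions were set by coding genes alone, so RNA genes can lie inside them. Tf2 retrotransposons (0 bins), mating-type genes (1 bin) and annotated origins (0 bins) could not be tested. Named regions were the 10 with the highest mean in each strain, the 10 with the largest difference in each direction among those that passed (or else the 5 with the smallest p), rad3 with its neighbours, markers of strain construction, rad52, cdc25, and up to 3 members of each list, of which the text gives a part. There were some departures. Long noncoding RNA genes were not used for names, bins inside rad3 were left out of the named regions because input DNA was missing there on some arrays, and regions from the blocked fit were added after their values had been seen. Of the 10 top regions in Δrad3, 1 is not reported here.

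Arrays of the same replicate number share a slide and a scan day per the file headers, so the slide block equals the replicate block. Deviations from the strain means correlated between same-numbered arrays at 0.472, 0.101 and 0.261 in IP/input (highest other pairs 0.0163, 0.118 and -0.140). In input they correlated at 0.742, 0.589 and 0.908 (highest other pairs 0.280, 0.404 and -0.549). The numbers thus pair the samples in input on all 3 slides, and in IP/input on slides 1 and 3 but not on slide 2. Alternatives covered background (normexp, offset 50, on median signals), loess, quantile normalization of input, A+T regression, filters on dim probes, bin size, scaling, centring, variance model, array weights, blocks, protocol text, thresholds, island definition and leaving out each array. The library labelled WT replicate 2 lacked rad3 signal, and fits without it and with the block were added after seeing the data.

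The limma steps were tested on simulated data of 12058 bins, with 200 changed bins in each of 5 simulations. For the difference between strains, a shift of 1 was recovered in 7.2% of changed bins and a shift of 2 in 85.8%, or 8.8% and 64.0% with the block. False calls made up 1.06% of calls, or 1.09% with the block. The fry test called the 322 island bins in 0% of 100 simulations with no shift and in 100% with a shift of 0.3, in simulations without correlation between bins.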

Results

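Rad52, a homologous recombination protein, was mapped by chromatin immunoprecipitation on tiling arrays in fission yeast (Schizosaccharomyces pombe) in early S phase. Cells carried cdc25-22, a temperature-sensitive allele of the mitotic inducer Cdc25. They were arrested for 4 h at 36.5 °C, released at 25 °C, given 6 mM hydroxyurea, which inhibits ribonucleotide reductase and slows replication forks, and harvested 60 min into the release. The series held 3 arrays labelled wild type (WT) and 3 labelled Δrad3, for a deletion in the gene of the ATR-family checkpoint kinase Rad3. Every array compared immunoprecipitated (IP) DNA with input DNA, and values are log2 IP/input with the array median at 0. No array carried a control IP, so unspecific IP signal is part of the levels in each strain. The comparisons asked where Rad52 lay in each strain, and whether its distribution differed without rad3. The median input signal over local background was 18.7, 13.1 and 3.51 on the arrays labelled WT replicates 1, 2 and 3, and 8.53, 11.8 and 5.16 on Δrad3 replicates 1, 2 and 3. For the IP it was 24.4, 11 and 3.41, and 15.5, 11.4 and 4.68, in the same order. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these arrays, and the number of arrays limits the precision.

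The deleted gene was examined first in the input DNA. rad3 lies on chromosome II at 904184 to 913629 on the forward strand, with its coding sequence at 904365 to 911525. The 9 probes at 909012 to 911114, inside the coding sequence, were not well above background on any of the 3 Δrad3 arrays, with mean log2 input signals of -5.50, -6.18 and -5.49. They were bright on WT replicates 1 and 3, at -0.41 and -0.64. On the library labelled WT replicate 2 they were not well above background either, at -6.18. The 15 probes at 904607 to 908759, in the upstream part of the coding sequence, were missing from the library labelled WT replicate 2 alone, at -6.25, against -0.17 to -0.23 on the other 5 arrays. The 8 probes at 911264 to 913288, at the downstream end of the annotated gene, were bright on all 6 arrays. A run of 24 of 33 rad3 probes was thus missing from the library labelled WT replicate 2, and a run of 9 from each Δrad3 array. The gap on the Δrad3 arrays thus covered only the downstream part of the coding sequence. That library went against its label at rad3, and it entered every WT value as labelled. Averaged over the gene, the limma difference between Δrad3 and WT was -0.0039 (SE 1.13, adjusted p = 1.00 over 4269 genes), and without that library it was -1.49 (adjusted p = 0.155).

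**Figure D1:**
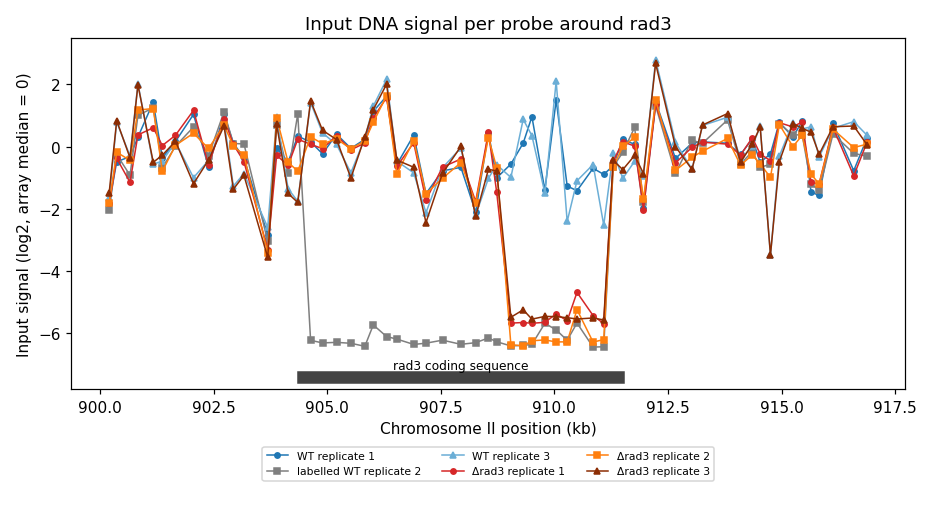
Input DNA signal (log2, array median at 0) of each probe against position on chromosome II (kb), with 1 line per array and the rad3 coding sequence as a bar. The 3 Δrad3 arrays dropped between 909012 and 911114, and the library labelled WT replicate 2 dropped from 904607 to 911114.

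Loci around rad3 and loci often altered in strain construction gave further values. swi1, which encodes a fork protection protein, overlaps rad3 on the other strand from 907370 to 914779, so its mean input signal was low on the same arrays (-3.31 on the library labelled WT replicate 2, and -2.05, -2.35 and -2.07 on Δrad3). The neighbour tor2 lay between -0.29 and -0.07 on all 6 arrays. The neighbour mxr2, with 2 probes, was low on all 6 arrays, at -1.61, -1.48 and -1.74 on the arrays labelled WT and -1.90, -1.85 and -2.25 on Δrad3. The input signal of ura4, a common selection marker, was 0.03, 0.77 and 0.25 on the arrays labelled WT and 0.71, 0.59 and 1.06 on Δrad3. That of his3 was 0.53 on the library labelled WT replicate 2, against -0.47 to -0.73 on the other 5 arrays. Input at leu1 ranged from -0.95 to 0.24 and at ade6 from -0.19 to 0.53. Rad52 IP/input at rad52 itself was 0.70 ± 0.09 in WT and 0.45 ± 0.17 in Δrad3 (SD, n = 3), and at cdc25 it was -0.17 ± 0.29 and 0.02 ± 0.13.

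In WT, the bins of highest Rad52 IP/input included tRNA, small nucleolar RNA and histone genes. The top 1-kb bin held thi2, a thiamine biosynthesis gene, and sec9 (II 3941001 to 3942000), at 1.83 ± 0.22 (SD, n = 3). It was followed among annotated bins by the arginine tRNA gene SPATRNAARG.01 with the proteasome gene rpt5 (I 3443001 to 3444000; 1.63 ± 0.66), the tRNA genes sup9 and imt07 (III 1689001 to 1690000; 1.61 ± 0.44) and the small nucleolar RNA gene snoU14 (II 1308001 to 1309000; 1.6 ± 0.17). The bin of the H2B histone gene htb1 and sec5 (III 1413001 to 1414000) stood at 1.48 ± 0.27, and the neighbouring H2A gene hta1 lay in the same region. The bin between SPCC61.05 and cbl1 (III 1452001 to 1453000) stood at 1.47 ± 0.30, the snoZ7 to snoZ3 cluster beside the GINS gene psf3 (I 527001 to 528000) at 1.41 ± 0.10, and the thiamine transporter gene thi9 with SPATRNAMET.02 (I 1484001 to 1485000) at 1.34 ± 0.22. Of these 8 regions, 4 held an AT-rich island, the sequence feature of fission yeast replication origins: those of thi2, SPATRNAARG.01, htb1 and the snoZ7 to snoZ3 cluster. Of the 8 top bins, only those of SPATRNAARG.01 and of that cluster overlapped an island, and none held an island midpoint. A further 2 of the top 10 regions, at I 4692001 to 4693000 (1.73 ± 0.42) and I 4002001 to 4003000 (1.48 ± 0.28), lie on the part of chromosome I that could not be matched to the annotation.

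By limma, 376 of 12058 bins in 255 regions were enriched in WT (adjusted p under 0.05 and mean log2 of at least 0.5). Of the 311 annotated ones, 17 held the midpoint of an AT-rich island, against 9.76 from independent lists. Without the library labelled WT replicate 2 the count was 110, of which 103 were among the 376. It was 941 without WT replicate 1, 73 without WT replicate 3, and 837 with the replicate number as a block. The block removes variation between slides from the error but not from a strain's mean. Blocked counts of enriched bins, in either strain or shared, thus come from too small an error. With normexp background correction, and with a trended robust variance, limma called 0 bins in WT. The IP carried the same dye on all arrays, so a dye bias is part of each strain's levels. Only the part of it that is equal on all arrays cancels between strains.

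In Δrad3, several of the bins of highest Rad52 IP/input held the midpoint of an AT-rich island. The top bin, an island between mug147 and SPBC56F2.05C (II 4106001 to 4107000), stood at 2.0 ± 0.41 (SD, n = 3), against 0.11 ± 0.49 in WT. Other such bins among the highest were ssd2 (I 1027001 to 1028000; 1.70 ± 0.39), the 5S rRNA genes SPRRNA.07 (III 2308001 to 2309000; 1.68 ± 0.42) and SPRRNA.54 (II 3097001 to 3098000; 1.61 ± 0.25), and the mRNA export gene mex67 (II 2410001 to 2411000; 1.63 ± 0.47). SPRRNA.07 lies in a raised stretch of chromosome III, where bins at 2293001 to 2313000 averaged 0.45, 0.59 and 0.72 on Δrad3. SPATRNAARG.01 with rpt5, at 1.77 ± 0.30 in Δrad3 and 1.63 ± 0.66 in WT, and the bin next to frg1 (II 2022001 to 2023000; 1.64 ± 0.68) overlapped an island without holding its midpoint. The bin of SPAC343.21 (I 1666001 to 1667000; 1.74 ± 0.67) overlapped none. A further top bin, I 5315001 to 5316000 (1.78 ± 0.38), lies where no names were assigned.

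By limma, 226 bins in 165 regions were enriched in Δrad3. Of the 192 annotated ones, 73 (38.0%) held an island midpoint, against 6.03 from independent lists, and these were 22.7% of the 322 measured island bins. With the replicate block the count was 680, with the trended robust variance 68, and without Δrad3 replicate 1, 2 or 3 it was 84, 86 or 32. Each strain's call draws on 1 pooled spread, and without the library labelled WT replicate 2 the Δrad3 count was 583, which held all 226. The strains shared 58 enriched bins, against 7.05 from independent lists, and 293 (47.2) with the replicate block. Probe and dye effects and unspecific IP signal common to all arrays are part of that overlap.

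Between strains, the bins of smallest p had higher values in Δrad3, and most of them were intergenic or AT-rich. Bins are given here in order of p, and some named below had larger differences. The first lies on the part of chromosome I left without names. At I 5315001 to 5316000 the values were -0.19, 0.09 and -0.03 on the arrays labelled WT and 1.43, 1.72 and 2.19 on Δrad3. The difference of 1.82 (SE 0.23) passed in limma (adjusted p = 0.0369). The next 4 bins in that direction did not pass without the replicate block, described below: the bin between the monopolin gene pcs2 and the stress regulator gene hsr1 (I 1955001 to 1956000; 1.54, adjusted p = 0.0599), the island between mug147 and SPBC56F2.05C (1.89, 0.0625), the Ras GTPase-activating protein gene gap1 (II 948001 to 949000; 1.43, 0.0655), and the bin between the NIMA-family kinase gene fin1 and the cyclin gene pas1 (I 1359001 to 1360000; 1.39, 0.0655). In the other direction limma called none without the block. The smallest p values were at aro2, the chorismate synthase gene (III 1876001 to 1877000; -0.96, adjusted p = 0.146), SPCC622.14 with SPCC622.15C (III 1429001 to 1430000; -0.83, 0.297) and sfk1 (III 868001 to 869000; -0.89, 0.297). Next came the cell wall glucan synthase gene ags1 (III 1375001 to 1376000; -0.78, 0.331) and htb1 with sec5 (-0.84, 0.357). Under other processing these differences came as close to 0 as -0.49, -0.27, -0.34, -0.16 and -0.21, in the same order.

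limma called 1 bin higher and 0 lower in Δrad3, with 842 bins (574 higher, 268 lower) at an unadjusted p under 0.05. With arrays scaled to 1 spread it called 104 higher and 1 lower, and with normexp background 71 higher and 0 lower. The values of the 2 strains did not overlap in 1601 bins (13.3%, where arrays that are not paired give 10% by chance), of which 839 were higher in Δrad3. Arrays of the same number shared a slide and a scan day. With the replicate number, and so the slide, as a block, 98 bins in 69 regions were higher and 1 was lower. The single lower one was aro2 (adjusted p = 0.0296). Without the library labelled WT replicate 2, and so with 1 array fewer, limma called 0 bins (917 at an unadjusted p under 0.05). The difference at I 5315001 was then 1.89 (SE 0.25, adjusted p = 0.0621). With the block as well, 278 bins were higher and 22 lower, with 95 of the 98 among the 278. Moderation gave that fit 34.4 degrees of freedom in all, against 14.4 in the blocked fit of all arrays. Its error was thus mostly borrowed from other bins, so its larger count is not evidence of more differences.

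The regions with the largest differences under the block were named after their values had been seen. They included mex67 (1.88, adjusted p = 0.0009 in limma with the block), the island between mug147 and SPBC56F2.05C (1.89, 0.0009), csk1, a CDK-activating kinase gene, with the phosphatidylinositol synthase gene pis1 (I 649001 to 651000; 1.71, 0.0037), the region at arv1 (I 1893001 to 1895000; 1.61, 0.0026), pmp3 (II 888001 to 890000; 1.53, 0.0421) and the bin between erm1 and rpa12, a gene of an RNA polymerase I subunit (III 1039001 to 1040000; 1.47, 0.0063). The bins of gap1 and between fin1 and pas1 passed with the block too (0.0046 and 0.0059). The region between pcs2 and hsr1 and the bin at I 5315001 passed as well (0.0043 and 0.0012). So did the regions at I 5264001 to 5266000 (1.59, 0.0037) and I 4597001 to 4599000 (1.48, 0.0098), which were not given names. On the library labelled WT replicate 2 the mex67 bin stood at -0.98 and the csk1 bin at -1.27, both below WT replicates 1 and 3. The bin at I 4597001 stood at -1.99 on it, against -0.47 and -0.59, and its difference was 0.99 without that library. Between erm1 and rpa12 that library stood at -1.07, against -0.34 and 0.02. The pmp3 bin spread widely in WT (0.08, -0.91 and -1.92), and with normexp background its difference was 0.41 (adjusted p = 0.699 in limma without the block).

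**Figure D2:**
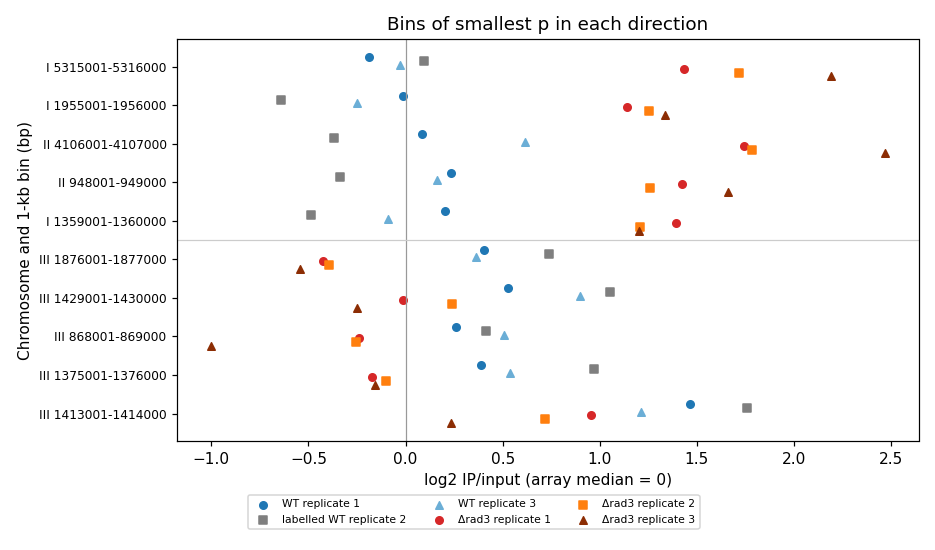
log2 IP/input (array median at 0) in the 1-kb bins of smallest p, with bins on the vertical axis and 1 point per array. In the upper 5 bins the Δrad3 arrays lie above all arrays labelled WT, as at I 5315001 (1.43 to 2.19 against -0.19 to 0.09). In the lower 5 they lie below, where no bin passed without the replicate block.

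At AT-rich islands, where fission yeast origins lie, the 322 island bins had a mean of 0.52 ± 0.15 in Δrad3 and 0.20 ± 0.22 in WT (SD, n = 3). Set against the array median, the list passed limma's fry test in Δrad3 (adjusted p = 0.019 over 15 lists) and not in WT (adjusted p = 0.177). Set against other bins in camera with an estimated correlation, it passed in neither strain (adjusted p = 0.0851 in Δrad3 and 0.415 in WT by limma's camera). The mean of the island bins minus that of all other bins was 0.39, 0.46 and 0.70 on the Δrad3 arrays (0.52 ± 0.16) and -0.07, 0.33 and 0.38 in WT (0.21 ± 0.25), where 0.33 belongs to the library labelled WT replicate 2. All 3 Δrad3 arrays lay above all 3 arrays labelled WT. The difference between strains in this excess was 0.31, or 0.46, 0.13 and 0.32 within slides 1, 2 and 3. It did not pass: an exact two-sided permutation test of the 6 values gave p = 0.1, the smallest it can give, and fry, which sets the change of the island bins against no change, gave an adjusted p of 0.240 (0.195 with the slide block). Without the library labelled WT replicate 2 the difference in the excess was 0.36, and limma's fry of the island bins gave an adjusted p of 0.310. The difference in the excess was 0.16 without WT replicate 1 and 0.14 among the arrays sharing 1 protocol text. Adjusted over the list alone, limma called 44 island bins higher and 0 lower, and 67 and 0 with the block, against 0 adjusted over all bins and 35 with the block.

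On the Δrad3 arrays the mean fell with distance from the islands. Within 1 kb of an island midpoint the mean was 0.35, 0.37 and 0.56 on the Δrad3 arrays, and at 1 to 2 kb it was 0.11, 0.09 and 0.17. On WT replicate 3 it was 0.25 and 0.09, and on WT replicate 1 -0.04 and 0.04. The library labelled WT replicate 2 had a broader profile, at 0.28 within 1 kb and still 0.14 at 5 to 6 kb. Set against bins of matched A+T content more than 2 kb from any island, the 267 island bins with a match stood 0.18 ± 0.17 higher in WT and 0.41 ± 0.16 in Δrad3, a difference of 0.23 (exact permutation p = 0.1). Among the 80 annotated bins higher in Δrad3 with the block, 35 (43.8%) held an island midpoint, against 2.51 from independent lists. Without the library labelled WT replicate 2, in the blocked fit that rests on slides 1 and 3, it was 54 of 217 (24.9%), against 6.81. The island with the largest difference between strains was that between mug147 and SPBC56F2.05C. The islands with the highest means over all arrays were those at SPRRNA.07 and between SPCC569.05C and SPCC569.03 (III 2428001 to 2429000). The latter stood at 2.60 on the library labelled WT replicate 2, -0.11 and 0.81 on WT replicates 1 and 3, and 0.84, 1.92 and 1.83 on Δrad3. Both lie in the raised stretch at the right end of chromosome III, given below. Bins of its outermost 20 kb averaged 2.34 on that library and 0.68, 1.33 and 1.62 on Δrad3. Around SPRRNA.07 (III 2293001 to 2313000) bins averaged 1.58 on that library and 0.45, 0.59 and 0.72 on Δrad3. Part of both means is thus shared with the bins around them.

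**Figure D3:**
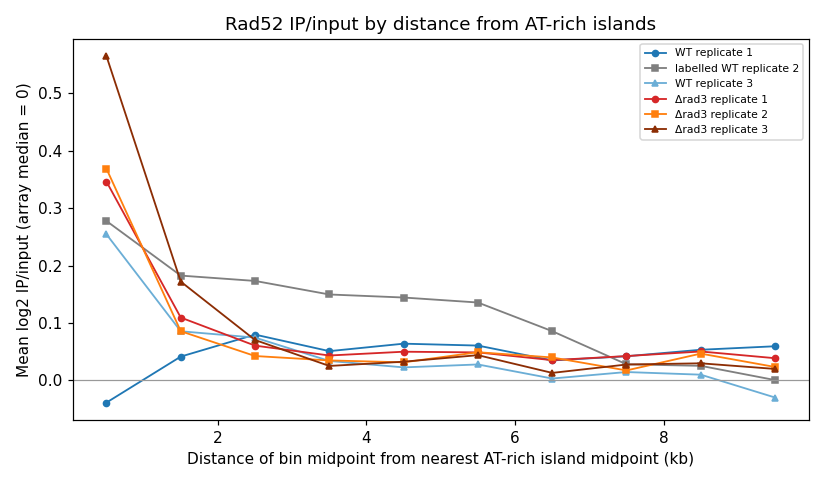
Mean log2 IP/input (array median at 0) against the distance of a bin from the nearest AT-rich island midpoint (kb), with 1 line per array. The Δrad3 arrays stood at 0.35 to 0.56 within 1 kb and at 0.09 to 0.17 at 1 to 2 kb, and the WT replicates 1 and 3 at -0.04 and 0.25 within 1 kb.

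Of the 15 region lists, 5 stood above the array median in IP/input in both strains. Without a control IP, Rad52 and unspecific signal cannot be told apart at these loci. tRNA genes stood at 0.40 ± 0.09 in WT and 0.38 ± 0.05 in Δrad3 (SD, n = 3), rRNA and 5S genes at 0.52 ± 0.12 and 0.58 ± 0.11, small nuclear and nucleolar RNA genes at 0.33 ± 0.07 and 0.26 ± 0.04, centromeres at 0.57 ± 0.28 and 0.85 ± 0.02, and convergent intergenic regions at 0.30 ± 0.07 and 0.21 ± 0.05. All 5 passed in both strains by limma's fry test, the largest adjusted p being 0.0129 for convergent regions in Δrad3. They also passed against other bins in camera with an estimated correlation, where the largest adjusted p was 0.0438. Within them, sup9 stood at 1.61 in WT and 1.02 in Δrad3, SPRRNA.40 at 0.88 and 1.51, and snoU14 at 1.6 and 1.09, whereas SPATRNATHR.01 stood at -0.09 and 0.97 and snR5 at -0.39 and 0.28. Those 2 WT means hold values of -1.11 and -0.93 on the library labelled WT replicate 2, against 0.23 and 0.62, and 0.09 and -0.32, on WT replicates 1 and 3. The convergent region between SPAC4A8.14 and the septin gene cdc3 stood at 1.22 and 1.05, that between atp25 and apm4 at -0.92 and -0.15, and the bins of centromere III at 0.70 and 1.23. Lists can share bins: the convergent region between tef3 and SPCC417.09C, at 1.27 and 0.91, includes the sup9 bin. Of 458 convergent regions, 83 were measured. At the centromeres, with 12 bins on chromosome II and 2 on III, the library labelled WT replicate 2 stood apart. Its mean there was 0.25, against 0.71 and 0.76 on WT replicates 1 and 3.

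Other lists passed fry in WT and not in Δrad3. Histone genes stood at 0.59 ± 0.24 in WT (adjusted p = 0.0198) and 0.23 ± 0.23 in Δrad3, with hta1 at 0.97 and 0.51 and htb1 at 1.08 and 0.35. Heat shock protein genes stood at 0.12 ± 0.06 (0.0185) and -0.01 ± 0.04, with the Hsp70 gene sks2 at 0.80 and 0.36 and hsp16 at 0.07 and 0.59. Ribosomal protein genes stood at 0.18 ± 0.09 (0.0241) and 0.03 ± 0.05, with rps2202 at 1.08 and 0.73 and rpl3602 at -0.37 and 0.63, where the library labelled WT replicate 2 stood at -1.15 and the other WT arrays at -0.03 and 0.06. Meiosis-specific genes stood at -0.05 ± 0.03 (0.0136) and -0.01 ± 0.00, with rec15 at 0.69 and 0.00. Divergent intergenic regions stood at -0.12 ± 0.09 (0.0419) and 0.05 ± 0.03, with the region between ddr48 and jmj1 at -0.11 and 1.17. Against other bins none of these 5 passed in WT with an estimated correlation (smallest adjusted p = 0.195 by camera). Without the library labelled WT replicate 2, with 1 array fewer, the unadjusted fry p in WT was no longer under 0.05 for histone genes, ribosomal protein genes and divergent regions, whose means were then 0.55, 0.13 and -0.15. Glycolysis and fermentation genes stood at 0.21 ± 0.24 and -0.01 ± 0.13, with tpi1, the triose phosphate isomerase gene, at 0.92 and 0.29 and adh1 at 0.67 and 0.17. Targets of the G1/S transcription factor MBF stood at -0.05 ± 0.19 and -0.09 ± 0.09, with the ribonucleotide reductase gene suc22 at 0.49 and 0.29 and rep2 at 0.28 and -0.20, where the library labelled WT replicate 2 stood at 0.90 and the other WT arrays at 0.15 and -0.22. The mitochondrial genome stood at -0.30 ± 0.28 and -0.15 ± 0.54, and subtelomeres at 0.13 ± 0.47 and 0.34 ± 0.14, and none of these 4 lists passed fry in either strain.

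The test of the strain difference itself called 0 of the 15 lists by fry, with the smallest adjusted p at 0.228, and 2 lists had an unadjusted p under 0.05. Those were heat shock protein genes (difference -0.13) and divergent intergenic regions (0.17), both with an adjusted p of 0.228 by limma's fry. With camera's preset correlation more lists passed, among them AT-rich islands and ribosomal protein genes (adjusted p = 8.1e-15 and 1.7e-05). No call held with an estimated correlation, where the smallest adjusted p was 0.306. Of the 15 lists, 6 were lower in Δrad3 on all 3 slides: histone, ribosomal protein, heat shock protein, glycolysis and fermentation, and small nuclear and nucleolar RNA genes, and convergent regions. A further 5 were higher on all 3: AT-rich islands, centromeres, divergent regions, meiosis-specific genes, and rRNA and 5S genes. Agreement on 3 slides also arises often by chance. On slide 2 both Δrad3 replicate 2 and the library labelled WT replicate 2 lacked rad3 signal. Among rRNA and 5S genes 46.9% of bins were higher, and the difference of 0.06 was 0.01 without the library labelled WT replicate 2. At centromeres the difference was 0.28, and 0.11 without that library. Histone genes differed by -0.32, -0.44 and -0.31 within slides 1, 2 and 3, for a difference of -0.36 that did not pass (adjusted p = 0.240 by limma's fry, and 0.191 with the block). Ribosomal protein genes differed by -0.15 (-0.13, -0.22 and -0.10). In the subtelomeres of chromosomes I and II the library labelled WT replicate 2 stood at 0.66 and WT replicates 1 and 3 at -0.08 and -0.21. The difference of 0.21 became 0.48 without that library. tRNA genes differed by -0.01 and MBF targets by -0.04.

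**Figure D4:**
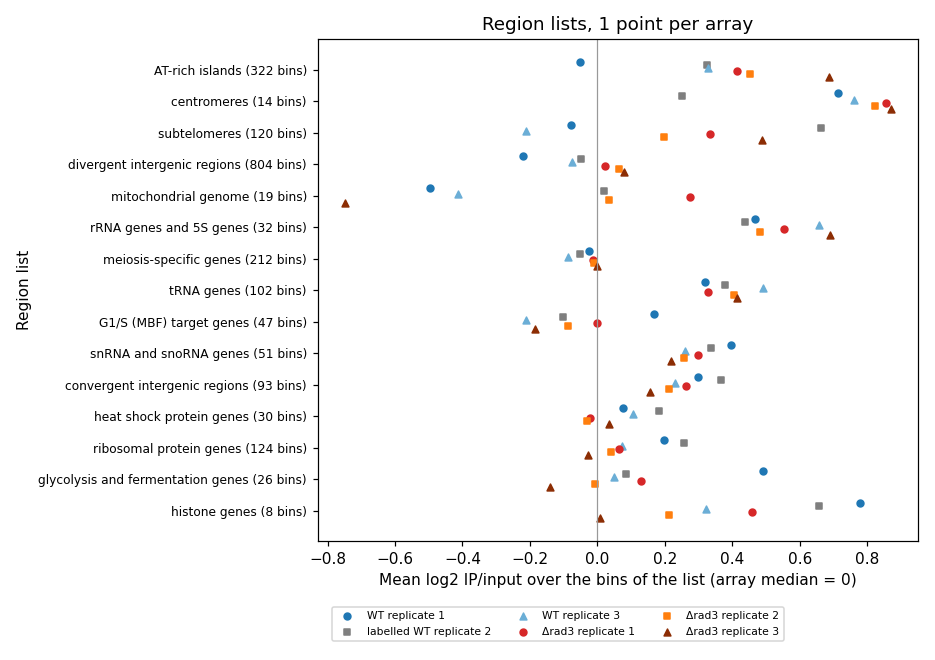
Mean log2 IP/input (array median at 0) over the bins of each of 15 region lists, with 1 point per array and the number of bins beside each list. For AT-rich islands the Δrad3 arrays (0.42 to 0.69) lie above the arrays labelled WT (-0.05 to 0.33), and for tRNA genes both strains lie between 0.32 and 0.49.

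Input DNA, which reports copy number as replication proceeds, was compared between strains in the same bins. At AT-rich islands, the input of island bins minus that of other bins was 0.35, 0.31 and -0.32 on the arrays labelled WT and 0.31, 0.28 and -0.22 on Δrad3. The difference between strains was 0.01 (exact permutation p = 0.9), within the spread of 0.38 and 0.30 (SD) inside the strains, and slide 3 stood apart from slides 1 and 2 in both. limma called 0 of 12056 bins with different input, with 8 at an unadjusted p under 0.05. Those 8 are 0.07% of bins, far below the share that chance gives at this threshold, so the fit had little power. The filter on dim probes had left out the 9 rad3 probes missing from all Δrad3 arrays. limma also called 0 with no such filter. With the replicate block it called 0 as well, with 449 at an unadjusted p under 0.05.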

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

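The 2 fits without the library labelled WT replicate 2 that also hold the replicate block were chosen after seeing the data. In those 2 fits the strain difference rests on slides 1 and 3. In the one without A+T regression, moderation gave 34.4 degrees of freedom in all, against 12.9 in the first fit. The other alternatives were planned. Fixed slide block and replicate block are the same fit here. At AT-rich islands in Δrad3 the excess over other bins stayed positive in all 26 alternatives (0.253 to 0.707), and the unadjusted fry p of the island bins against the array median stayed under 0.05. Against other bins, with an estimated correlation, the list did not pass in the first fit (adjusted p = 0.0851 by limma's camera). The input fit called 0 bins in all 24 of its alternatives (limma), with the little power described above. Where a value moved, the cause was not tested, except that fits without an array hold fewer samples.

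The count of bins differing between strains, 1 at first, was 99 with the replicate block, 95 with the replicate block and A+T regression, and 87 with the slide as a random block. It was 71 with normexp, 4 with loess, 2 with single probes, 105 (104 higher, 1 lower) with arrays scaled to 1 spread, 9 when centred on coding genes, 14 with array weights and 41 among arrays sharing 1 protocol text, where WT has 1 array assumed to vary like the others. A+T regression leaves out the unannotated part of chromosome I, and so the bin called at first. limma called 0 with A+T regression, 2-kb bins and the trended robust variance, and 0 to 1 when leaving out each array. The added fits without WT replicate 2 gave 300 (278 higher, 22 lower) with the block and 150 with A+T regression as well.

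Enriched bins in WT (376) numbered 0 with normexp, 0 with the trended robust variance, 210 in 2-kb bins, 152 with array weights, 837 with the replicate block, 692 with the block and A+T regression, and 53 at a mean log2 of at least 1. Leaving out each array gave 73 (without WT replicate 3) to 941 (without WT replicate 1), and 110 without replicate 2. In Δrad3 (226) they numbered 133, 657, 680, 530 and 105 under 2-kb bins, weights, block, block with A+T and the stricter threshold, and 839 with scaling, 68 with the trended variance, 745 with 1 protocol text, 761 and 555 in the added fits, and 32 (without Δrad3 replicate 3) to 583 on leaving out each array. Shared bins (58) numbered 0 with normexp and the trended variance, 29 in 2-kb bins, 150 with scaling, 94 with weights, 293 with the block, 244 with A+T as well, 148 with 1 protocol text, 10 at the stricter threshold, 90 when a bin within 1 kb counted, 165 and 100 in the added fits, and 9 to 118 on leaving out each array.

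The island difference between strains (0.305) stayed positive in all 26 alternatives, and was 0.138 with 1 protocol text. It was 0.441 with normexp, 0.449 with scaling, 0.152 with islands from 500-bp windows and 0.333 in the added fit with A+T regression, and in these 4 the unadjusted fry p of the island bins' change against no change fell under 0.05. It ranged from 0.163 to 0.389 on leaving out each array. The WT excess over other bins was 0.213, from 0.0292 with normexp to 0.381 with 1 protocol text, and the unadjusted fry p of the island bins against the array median fell under 0.05 only without WT replicate 1 (excess 0.356, against 0.129 to 0.356 on leaving out each array). Region lists that differed numbered 1 with normexp and 1 with 2-kb bins, and the block changed no list call.

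The strain difference in input at islands was 0.448 with 1 protocol text. It turned sign with normexp (-0.0835), 500-bp bins (-0.0118), single probes (-0.0072) and islands from 500-bp windows (-0.0232), and ranged from -0.205 to 0.185 on leaving out each array. The rad3 input difference (-0.0039) turned sign with normexp (0.132) and array weights (0.515). It ranged from -1.49 without WT replicate 2 to 0.750 without WT replicate 1, and passed only in the added fit with the block (-1.42, limma adjusted p = 0.0236). Over named regions and their alternatives, each bin was counted once per comparison. Of these calls, 731 were unchanged, 97 gained and 40 lost the threshold, and none turned direction. These bins were chosen on the same arrays for high means, small p or large differences, so an unchanged direction was likely from the start. Signal over background was lowest on slide 3 (3.51 and 5.16 in the input), where the values of single bins are least precise.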

Other observations

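Chosen after the results were seen were the tests of a swap and of a wrong label at rad3, of A+T content and the library labelled WT replicate 2 at islands, and of input at the end of chromosome III. The tests of failed spots, of input at islands, of A+T content at that chromosome end and of other splits were chosen before.

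The right end of chromosome III carried a broad domain of Rad52 signal on some arrays. Over the last 50 kb covered (III 2383001 to 2433000, 47 bins) log2 IP/input was 2.13 on the library labelled WT replicate 2, 0.08 and 0.17 on WT replicates 1 and 3, and 0.66, 1.24 and 1.41 on Δrad3. Single loci there and further inward showed it too. The ribosomal protein gene rpp103 stood at 2.28 on that library and at 0.04 and 0.38 on WT replicates 1 and 3. Inward of those 50 kb, mug9 (III 2369001 to 2370000) stood at 2.26, 0.03 and 0.12 on the same arrays. The divergent region between spx2 and ppk38 stood at 2.57 on that library, and at 0.71, 1.28 and 1.39 on Δrad3. The signal declined inward over 200 kb, from 2.34 in the outermost 20 kb to 0.94 in the innermost on that library, and from 1.62 to 0.17 on Δrad3 replicate 3. The right end of chromosome II, with the phosphate transporter gene pho84 and the galactose genes gal1, gal7 and gal10, stood at 1.10 on that library and at 0.13 on both other WT arrays. The right end of chromosome I (I 5517001 to 5553000) stood at 1.17 on that library and at -0.24 and -0.47 on the other WT arrays. On Δrad3 it stood at 0.49, 0.34 and 0.75. The left end of chromosome III stood at 0.51 on that library, and at 0.01 and 0.30 on the other WT arrays. The left end of chromosome II went the other way, at -0.52 on that library, -0.20 and -0.24 on the other WT arrays, and 0.18, 0.03 and 0.24 on Δrad3.

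Outside rad3, 1 probe was not well above background in the input of all 3 Δrad3 arrays and bright on all arrays labelled WT. It lies at II 2115566, beside the mating-type gene mat1-Mc (II 2114482 to 2115027), with log2 input of -5.60, -6.12 and -5.56 in Δrad3 and -1.29, -1.22 and 1.86 in WT. Its neighbour at II 2115739 was bright on all 6 arrays. At this probe the library labelled WT replicate 2 went with its label.

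The loss of rad3 signal from the library labelled WT replicate 2 was weighed first. Failed spots are argued against, since the longest run of missing neighbouring probes elsewhere on that array was 2, against 24 in rad3. A swap with a Δrad3 array is argued against as well, because 0 of the 3 Δrad3 arrays held an intact rad3 and their gap was shorter. All 24 probes were missing from the IP channel too, which is consistent with a single wrong label or a strain lacking the rad3 coding sequence. The 15 upstream probes were bright on all 3 Δrad3 arrays. A wrong label would thus have to hide a strain with a longer gap than theirs. Which of these holds stays open, and no biological explanation was tested.

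The 35 AT-rich island bins higher in Δrad3 with the slide block differed by 1.23 ± 0.25 (SD over bins). After A+T regression in the same blocked fit all 35 were still called, at 1.16 ± 0.25, which argues against base composition as the whole cause, and input over these bins was 0.15 ± 0.17 higher in Δrad3, so a lower input does not account for the ratio. Without the library labelled WT replicate 2, 34 of the 35 were still called. That blocked fit rests on slides 1 and 3, whose arrays also entered the choice of the 35. Its error was also mostly borrowed from other bins, so the 34 calls cannot decide whether that library was a source. WT replicates 1 and 2 carry another protocol text than Δrad3, and WT replicate 3, the only WT array with the text of Δrad3, stood at 0.12 in these bins, against 1.01, 0.90 and 1.47 on Δrad3 (over all islands, the difference between arrays sharing 1 text was 0.138, against 0.305). WT replicate 1 and the library labelled WT replicate 2 stood at -0.07 and -0.38, although the latter lacked rad3 signal. The bins were chosen with that library counted as WT, so its low value cannot decide on an effect of rad3. Only 1 WT array shares the text of Δrad3, and the bins were chosen for the difference. A difference in preparation and an effect of the rad3 deletion thus both stay open, and neither was tested.

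For the chromosome III end, input on the library labelled WT replicate 2 differed from the mean of the other 5 arrays by 0.0365 (log2), far less than its IP/input of 2.13, which argues against a lower input. After A+T regression the value was 2.14, which argues against base composition. The Δrad3 arrays lay between that library and the other WT arrays. All libraries that lacked rad3 signal (2.13 on that library, and 0.66, 1.24 and 1.41 on Δrad3) thus stood above WT replicates 1 and 3 (0.08 and 0.17). That split by rad3 signal was not tested. A strain difference and a difference in how cells or chromatin of single cultures were prepared may both contribute, and neither was tested.

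The 6 arrays divide into 3 and 3 in 10 ways, too few for a share under 0.05. By limma the real division gave 1 differing bin and the highest of the others 0, so 1 of 10 gave as many. With the slide block, 4 divisions part all 3 slides, also too few: the real one gave 99 bins and the highest of the others 0, so 1 of 4 gave as many. Region lists and input bins were called 0 times in the real division and in the highest of the others, that is in 10 of 10 for each.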
